A study of Mus musculus with 8 samples.

How the data were processed

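Polyadenylated RNA of FACS-sorted mouse spermatocytes and round spermatids (C57BL/6, Hoechst staining) was sequenced from Larp7 conditional knock-out and control animals, with 2 libraries per genotype and stage and 8 libraries in all, per the labels. The labels call the 2 libraries of a group biological replicates but do not say that each came from its own animal. The p-values of limma and the quasi-binomial test therefore measure the spread between these libraries. Exact binomial and Fisher's exact tests count exons, introns, sites or genes as independent and hold no spread between libraries. A shift of a whole library moves many of them together, so these tests describe the libraries at hand only.

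Per the submitters' processing notes, reads were aligned with STAR and mm10 is the genome build; versions are not given in the sources used here. The files analysed were 10 deposited tables of alternative splicing events, 1 per stage and event type: cassette exons (SE), mutually exclusive exons (MXE), alternative 3 prime splice sites (A3SS), alternative 5 prime splice sites (A5SS) and retained introns (RI). Per the file headers, each row holds inclusion and skipping read counts of 2 sample groups, the lengths of both forms, inclusion levels as fractions, the level difference, and a p-value with its FDR from the authors' own test. Each deposited count cell joins the values of 2 libraries with a comma, so it is not a plain count column. The inclusion form length was the length of the alternative part plus 149 in every row, and inclusion levels recomputed from the deposited read counts and form lengths lay within 0.0005 of the deposited fractions. Inclusion of a mutually exclusive pair stands for its first exon on the plus strand and its second on the minus strand. No gene expression table was used here.

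The headers number the sample groups and do not name their genotype. Differences within a stage are therefore given as the first minus the second sample group of a table, with no genotype direction, and the planned test of the genotype difference between stages was not run. The stage of each table is given by the labels, so the stage comparison carries its direction.

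Reads over the events of all types summed to between 51786242 and 102000320 per spermatocyte library and between 49904607 and 93265932 per round spermatid library. Overlapping events share reads, so these sums exceed the reads sequenced, and library totals are unknown. The second library of the first sample group was the deepest in both stages.

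Events were tested when inclusion plus skipping reads averaged at least 10 per library and each form had a read. Log2 odds of inclusion, normalised by form length, were fitted with limma 3.58.1 in R 4.3.3, weighted by the inverse counting variance. The moderated spread (eBayes with a trend) followed the mean reads of the rarer form. An average of 0.5 reads was added to each form, scaled to the reads of the event in each library. P-values were adjusted by Benjamini-Hochberg over all tested events of the 5 types, and events with an adjusted p below 0.05 were called. The stage comparison used events present in both tables and a 4-group fit of the 8 libraries. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

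This fit differs from the one written before the data were examined. The design named a trend on coverage and 0.5 reads added to each form. Read literally, with the trend on total reads and unscaled 0.5 reads, it called 0 events in spermatocytes and 0 in round spermatids. Both changes were made after these counts had been seen, on the ground of simulated data. Without true differences the trend on total reads gave 3.73% of spermatocyte events with over 32 reads of the rarer form a p under 0.01, against 0.00622% of those with at most 1 such read. The rarer-form trend gave 0.768% and 0.056%. Over all spermatocyte events the shares were 0.84% and 0.273%. Both trends were compared here with scaled reads. With 200 changed events the literal fit made 34 false calls in the spermatocyte setting and 11 in the round spermatid setting. It recovered 24.5%, 64.8% and 72.5% of spermatocyte events changed by 1, 2 and 3 units, and made 18 false calls in the stage setting. Without true differences the trend on total reads made 0 calls in spermatocytes and 1 in round spermatids, and the rarer-form trend 0 in both. All simulated events of a setting shared 1 spread, so the simulation cannot settle which fit suits the real tables. Scaling was added because, with the rarer-form trend and unscaled reads, the stage setting gave 171 false calls against 17 with scaling. Unscaled reads recovered more true changes, 32.7% against 14.3% of the smallest in spermatocytes, with 9 false calls. The trend of the planned quasi-binomial test was changed in the same way, which took its calls from 39 to 178 in spermatocytes and from 9 to 122 in round spermatids. In all, 15 versions of the tests were run on the real tables while the fit was being set. Their calls ranged from 0 to 3565 in spermatocytes and from 0 to 472 in round spermatids, with 0 calls in 3 and 4 versions. Genotype calls are therefore conditional on a choice made with the data in view.

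Changed events in simulated data, 200 per comparison, were drawn among those averaging at least 5 reads of each form. Recovery with fewer reads was not measured. The reported fit was tested on these data. Of events changed by 1, 2 and 3 units of log2 odds it recovered 14.3%, 66.2% and 73.8% in the spermatocyte setting, with 0 false calls. In the round spermatid setting it recovered 21.9%, 64.3% and 93.9%, with 0 false calls. In the stage setting it recovered 43.9%, 75.0% and 90.9%, with 17 false calls, so its false share exceeded 5%.

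Gene abundance was approximated by the reads of the most covered event of each gene, as log2 CPM, reads scaled to the library sum of these, with 0.5 reads added, in limma with a trend. It depends on the splicing of that event. In simulated data this fit made 5 false calls in the spermatocyte setting and 11 in the round spermatid setting. Gene lists, fixed before the data were examined, were 7SK and U6 snRNP, core spliceosome, splicing regulators, meiotic chromosome and recombination, piRNA and germ granule, acrosome and spermatid differentiation, flagellum and cilium, chromatin regulators, and markers of spermatogonia, Sertoli cells, Leydig, peritubular and immune cells, and elongating spermatids. Lists were compared with all other tested genes by two-sided Fisher's exact tests, adjusted over lists and stages. Directions were tested with exact two-sided binomial tests that counted each alternative exon, intron or site once, and exon lengths with Fisher's exact tests.

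Named events were chosen by a rule fixed before the data were examined. Larp7 came first. Per stage followed the 12 called events with the largest inclusion difference, of at least 10 percentage points, with non-overlapping library levels and a mean of at least 20 reads. Each gene entered with its event of smallest p, so Larp7 entered with an intron in spermatocytes and with a cassette exon in round spermatids. Up to 3 further called genes of each list came next. Between stages the 6 called genes with the smallest p and up to 2 per list were named. For marker lists the 3 members with the most reads were named. Other genes named for abundance, and the Larp7 exon described first and drawn, were chosen after their values were seen: that exon had the largest difference among the Larp7 cassette exons, and of its events the one with the most reads was taken. Alternatives covered the test, weights, read minimum, adjustment, reads added, libraries, background and scaling. Those chosen after seeing the data were the trend on total reads, the unscaled 0.5 reads, the quasi-binomial test with a trend on total reads, filters on the rarer form and on the inclusion level, position in the cell as a covariate, the authors' calls for directions and lists, and abundance and the share of lower cassette exons without each library. The tests of gene lists between stages, with and without matched coverage, were also chosen after seeing the data. The test of X-linked genes for abundance was not in the design.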

Results

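RNA splicing was measured in spermatocytes, the germ cells in meiosis, and in round spermatids, the haploid cells that follow, from control mice and mice with a conditional knock-out of Larp7. Larp7 is an RNA-binding protein of the 7SK ribonucleoprotein that also takes part in U6 snRNA modification. Each of the 4 groups of genotype and stage held 2 libraries. The spermatocyte tables held 66122 events in 11283 genes, of which 61123 in 9861 genes were tested. The round spermatid tables held 52897 events in 10855 genes, of which 48060 in 9315 genes were tested. Groups within a stage are called the first and second sample group, as numbered in the deposited tables, because their genotype is not named there. Event reads came to 51786242 and 102000320 in the first and 64657689 and 64421409 in the second sample group of spermatocytes, and to 49904607 and 93265932 against 58487298 and 56164530 in round spermatids. For these groups both libraries' values are given in place of a mean and SD.

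The targeted gene was examined first in every library, and 3 of its 7 tested events were called in spermatocytes. A 125-nt cassette exon of Larp7 (ENSMUSG00000027968.11, mm10 chromosome 3, 127544154 to 127544278, minus strand) was included at 2.4% and 1.0% in the first sample group of spermatocytes and at 100% in both libraries of the second. In the first group, 17 and 18 inclusion reads stood against 376 and 1020 skipping reads. In the second, 6720 and 5947 inclusion reads stood against 0 skipping reads in each library. In round spermatids the exon was included at 0.3% and 0.6% in the first sample group and at 100% in both libraries of the second. The skipping difference was called by limma in both stages (adjusted p = 0.0002039 and 0.02265). Because Larp7 is the targeted gene, this difference cannot be told apart from a deletion of the exon itself, so it need not be a change of splicing. Larp7 reads were also lower in the first sample group. The log2 difference was -2.47 (SE 0.14, adjusted p = 1.656e-06) in spermatocytes and -1.99 (SE 0.20, adjusted p = 0.0004157) in round spermatids. An 85-nt Larp7 intron (127547005 to 127547089) was retained at 31.7% and 28.2% against 7.12% and 8.50% in spermatocytes (adjusted p = 9.095e-22). In round spermatids the same intron stood at 9.12% and 6.16% against 3.85% and 4.08% and was not called (adjusted p = 0.1916).

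**Figure D1:**
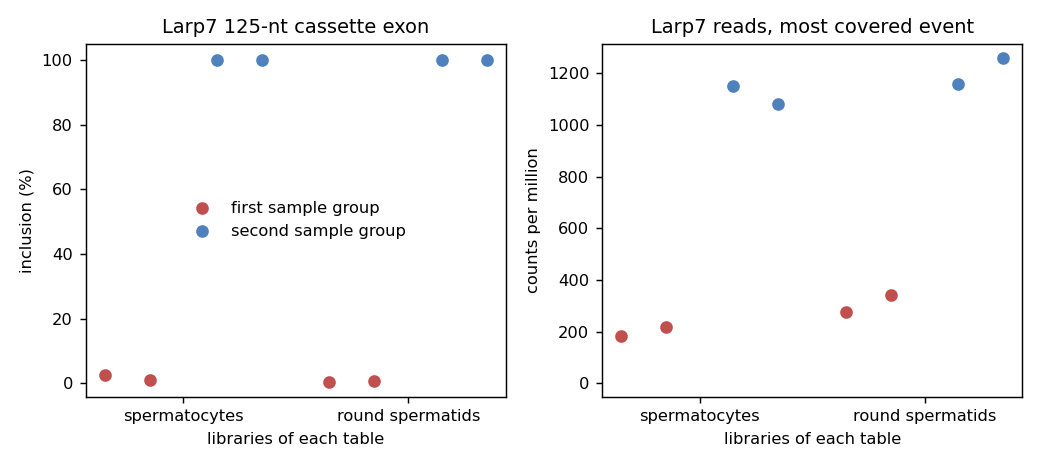
Inclusion of the 125-nt Larp7 cassette exon in percent (left) and reads of the most covered Larp7 event in CPM (right), 1 point per library, by stage and sample group. The 4 libraries of the first sample groups lie at 2.4% inclusion or lower and those of the second at 100%.

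Whether splicing differed between the genotype groups was asked in spermatocytes first, where 322 events in 250 genes were called. Transcripts of splicing factors were among them. Srsf5, an SR protein, had an intron (chromosome 12, 80947866 to 80949094) retained at 14.7% and 14.0% in the first sample group and at 30.5% and 25.1% in the second (limma adjusted p = 2.608e-10). An Srsf6 intron (chromosome 2, 162932143 to 162933425) stood at 21.2% and 27.5% against 41.8% and 49.8% (adjusted p = 6.65e-07). Inclusion of a cassette exon of Rbm5, a regulator of exon choice, was 57.3% and 61.0% against 79.0% and 77.2%. A cassette exon of Clk4, a kinase of SR proteins (chromosome 11, 51268165 to 51268231), went the other way, at 49.8% and 41.9% against 14.3% and 20.9%. The quasi-binomial test also called these Srsf5, Srsf6, Rbm5 and Clk4 events. Without count weights they were no longer called. Leaving out any library also removed their calls, though each kept its direction.

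At least 10 percentage points separated the groups in 138 of the called events, and in 136 of these the library levels did not overlap. Besides Larp7, and with each gene entered by its event of smallest p, the largest differences lay in Gm5458 (56.9 points, first minus second), Adgrl1 (-48.6), Ssbp4 (36.3), Mettl17 (-33.8), Tfam (33.1), Bscl2 (-31.5), Pex7 (29.8), Ncaph (-28.9), Clk4 (28.3), Ist1 (-27.6), U2surp (26.8) and Rsrp1 (24.7). The quasi-binomial test did not call the events of Tfam, Pex7 and Ncaph. Gm5458 belongs to a family of near-identical copies, so its reads are uncertain. The retained intron of Ist1 (chromosome 8, 109675425 to 109676757) fell from 64.1% and 60.9% in the second group to 34.3% and 35.4% in the first. A 45-nt exon of Rsrp1 (chromosome 4, 134925777 to 134925821) rose from 9.06% and 9.63% to 32.7% and 35.4%. These calls depend on the trend, which was chosen after the counts of calls were seen: with the trend on total reads 0 events were called, as with the literal reading of the design and without either library of the second sample group. With filters on the rarer form or the inclusion level, robust moderation, 8 libraries or a position covariate, the trend on total reads and unscaled reads called between 17 and 3565. In simulated data, where all events shared the same spread, the literal reading made 34 false calls and the reported fit 0. That does not settle which fit suits the real tables. Leaving out the first or the second library of the first group gave 11388 and 11517 with 1 residual degree of freedom. Of the tested events 5354 had an unadjusted p under 0.05 where uniform p-values would give 3056, and the quasi-binomial test called 178. In simulated data without true differences 0.273% of events had a limma p under 0.01, so p-values without true differences need not be uniform.

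**Figure D2:**
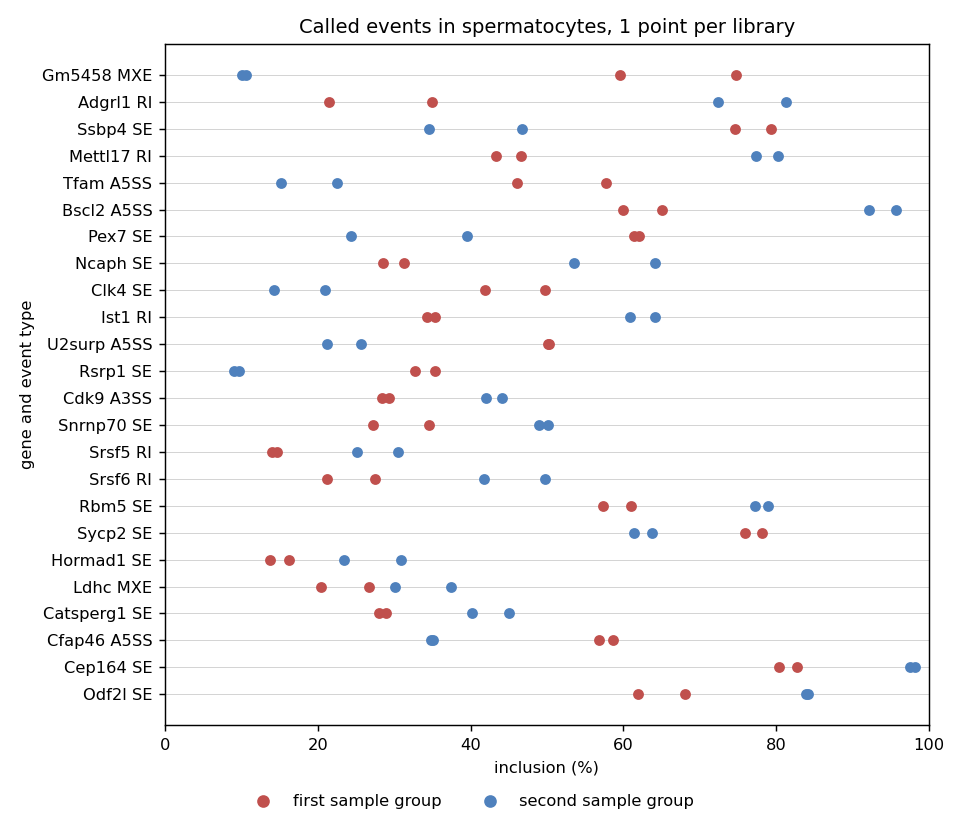
Inclusion in percent of the named events called in spermatocytes outside Larp7, 1 point per library and 1 line per event, by sample group. Libraries of the sample groups do not overlap in any event shown, and the difference was largest in size in Gm5458 (56.9 points) and smallest in Ldhc (-10.2 points).

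By list, 9 of 58 tested splicing regulators had a called event in spermatocytes (15.5% against 2.46% of other genes, Fisher's exact test, adjusted p = 0.0003235). They were Bclaf1, Clk3, Clk4, Hnrnpa2b1, Rbm25, Rbm39, Rbm5, Srsf5 and Srsf6. Adjusted over the list alone, 18 of its genes had a called event. With genes matched on coverage the enrichment ended (adjusted p = 0.2677), and genes called in the authors' deposited table did not show it (adjusted p = 0.06962). Of 25 genes of the 7SK and U6 snRNP list, Larp7 and Cdk9, the kinase of P-TEFb, were called; adjusted over the list alone, 2 were. An alternative 3 prime site of Cdk9 was used at 28.4% and 29.3% against 42.0% and 44.1%, a difference that the quasi-binomial test did not call. Of 38 core spliceosome genes 2 were called, and 5 adjusted over the list alone. A cassette exon of Snrnp70, a U1 protein, was included at 27.2% and 34.5% against 49.0% and 50.2%.

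Of 59 meiotic genes 4 had a called event, Hormad1, Spo11, Stag3 and Sycp2, and 4 adjusted over the list alone. A 35-nt exon of Sycp2, a lateral element protein of the synaptonemal complex, was included at 75.9% and 78.1% against 61.4% and 63.7%, and an exon of Hormad1 at 13.8% and 16.2% against 23.4% and 30.9%. Of 45 acrosome and spermatid genes 5 were called, and 9 adjusted over the list alone. Catsperg1, a subunit of the sperm calcium channel, had an exon at 29% and 28.0% against 45.1% and 40.2%. Ldhc, the germ cell lactate dehydrogenase, had an exon pair at 20.4% and 26.7% against 37.4% and 30.1%, which the quasi-binomial test did not call. Of 117 flagellum and cilium genes 8 were called, and 8 adjusted over the list alone. Among them were Cep164 (80.4% and 82.7% against 97.5% and 98.2%), Odf2l (68.1% and 61.9% against 83.9% and 84.2%) and Cfap46 (56.8% and 58.7% against 34.8% and 35.1%). In the piRNA list 1 of 26 genes was called, Rnf17, which was also the 1 adjusted over the list alone. None of the 83 chromatin regulators had a called event by limma, and 0 did adjusted over the list alone or by the quasi-binomial test. The marker lists of spermatogonia, Sertoli cells, Leydig, peritubular and immune cells, and elongating spermatids had 0 genes called by limma and by the quasi-binomial test; adjusted over the list alone, Stra8 was the 1 called. None of the lists after the splicing regulators passed adjustment.

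Called cassette exons in spermatocytes were mostly skipped more in the first sample group: 163 were lower there and 37 higher (exact binomial test, adjusted p = 4.582e-19). Called introns were mostly retained less, with 37 lower and 11 higher (adjusted p = 0.001111), a difference the quasi-binomial calls did not pass (adjusted p = 0.05634). Mutually exclusive exons (16 lower, 18 higher), alternative 3 prime sites (6 and 7) and alternative 5 prime sites (12 and 8) did not depart from an even split. Mean cassette exon inclusion was 88.98% and 89.32% in the first group and 90.08% and 90.01% in the second. Called cassette exons had a length divisible by 3 in 49.5% of cases, against 38.6% of other exons (Fisher's exact test, p = 0.001713). Called and other exons were not matched on coverage, so the contrast may follow from which exons can be called. Exons of at most 27 nt made up 2.50% of called and 1.23% of other exons (Fisher's exact test, p = 0.1043), and 5.13% of called exons with at least 10 points (exact p = 0.01618). In round spermatids 52.3% of called and 40% of other exons were divisible by 3 (Fisher's exact p = 0.1227), and 42.1% against 40.1% with at least 10 points. Between stages 37.2% and 40.7% were (exact p = 0.001637), the opposite direction to spermatocytes. Called exons with at least 10 points between stages had 39.4% against 40.4% of others (exact p = 0.5974). By the authors' FDR below 0.05 and a difference of at least 0.1, spermatocytes had 43.6% against 38.5% (exact p = 0.003375). Round spermatids had 39.8% against 40.1% by these calls (exact p = 0.9578).

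In round spermatids 63 events in 48 genes were called, 28 of them with at least 10 percentage points, and the libraries of these 28 did not overlap. Besides Larp7 the largest differences lay in Ccdc7a (44.6 points, first minus second), Gm5458 (44.2), Gsap (-39.9), Ccdc122 (38.3), Ssbp4 (36.2), Fnbp4 (-32.2), Osbpl1a (-30.4), Trmt10a (26.1), 1700029B22Rik (-25.7), Dnm2 (21.2) and Sirt3 (20.8). An intron of Gsap (chromosome 5, 21270615 to 21271216) was retained at 27% and 28.9% against 68.5% and 67.1% (limma adjusted p = 2.954e-05). A 12-nt exon of Dnm2, the dynamin of endocytosis (chromosome 9, 21490658 to 21490669), was included at 91.2% and 88.2% against 71.4% and 65.6% (adjusted p = 3.776e-08). Levels of Ccdc7a nearly met, at 94.3% and 29.6% against 26.7% and 7.99%, and without the first library of the first group the log2 odds difference was 0.63 and not called. Of called cassette exons 31 were lower in the first group and 13 higher (exact binomial test, adjusted p = 0.03187).

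By list, Clk3 was the 1 of 58 splicing regulators called, Akap3 the 1 of 119 flagellum genes, and Catsper1 and Gapdhs the 2 of 46 acrosome and spermatid genes; adjusted over the list alone 1, 1 and 5 genes were called. Larp7 was the 1 of 23 in the 7SK and U6 snRNP list, also adjusted over the list alone. Core spliceosome, meiotic and piRNA genes had 0 called, also adjusted over the list alone and by the quasi-binomial test. Chromatin regulators had 0 by limma and 1 by the quasi-binomial test. Gapdhs was also the 1 of 7 elongating spermatid markers, with 5 adjusted over the list alone, and the other marker lists had 0 by limma, by the quasi-binomial test and adjusted over the list alone. No list passed adjustment. The literal reading of the design called 0 events, as did leaving out either library of the second sample group, while leaving out the first or the second library of the first group gave 6663 and 3903. Dividing the same libraries by their position within each table cell called 335 events, more than the 63 of the sample groups. Tested events with an unadjusted p under 0.05 numbered 2443 where uniform p-values would give 2403. In simulated data without true differences 0.303% of events had a limma p under 0.01, so 2403 may be too high a baseline.

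The stages shared 18 called genes where 1.44 are expected from independent lists (Fisher's exact test, p = 6.066e-16), and 18 called events where 0.467 are expected. Every one of these 18 events differed in the same direction by header order. Among the shared genes were Larp7, the kinase gene Clk3, Dnm2, the sperm surface genes Adam3 and Adam32, the calcium channel gene Catsperd, Ssbp4 and Trmt10a. The quasi-binomial test did not call Clk3 and Trmt10a in both stages. Whether the difference itself differed between stages was not tested.

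**Figure D3:**
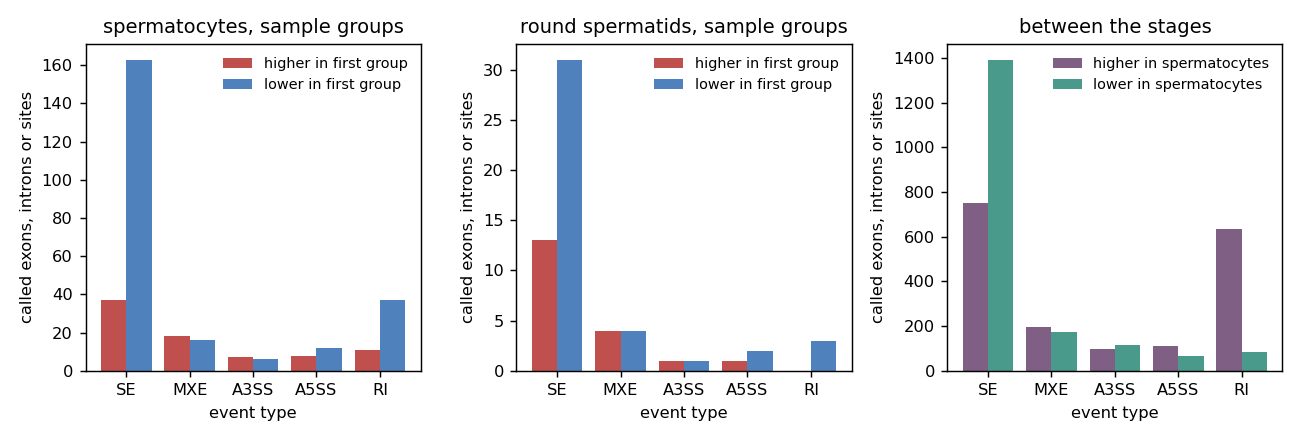
Number of called exons, introns or sites by event type and direction, in spermatocytes (left), round spermatids (middle) and between the stages (right). Called cassette exons (SE) were lower in the first sample group in 163 cases in spermatocytes, and 636 introns (RI) were higher in spermatocytes than in round spermatids.

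Reads of the most covered event of each gene served as a measure of abundance. In spermatocytes 546 of 9861 genes were called by limma, 464 higher in the first sample group and 82 lower. The median of all genes lay at 0.16 (log2), and median-ratio scaling, which brought it to 0.01, gave 488 higher and 281 lower. Genes of early germ cells were higher in the first group. Of 10 spermatogonia markers 5 rose (adjusted p = 0.001122 for the list, 9 higher and 1 lower adjusted over the list alone), namely Dmrt1, Sohlh1, Sohlh2, Stra8 and Uchl1. Sohlh2 stood at 27.7 and 13.4 CPM (reads scaled to the library sum of the most covered events) against 2.76 and 3.85 (2.56, SE 0.39). Uchl1 stood at 99.4 and 27.4 against 12.8 and 12. Tuba3a, the marker with the most reads, had a difference of -0.45 and was not called. Of 6 Sertoli cell markers 3 rose, Clu (1.36), Ctsl (2.01) and Cst9 (1.88; adjusted p = 0.01489 for the list), and 4 adjusted over the list alone. Leydig, peritubular and immune markers had 0 of 6 called by limma, also adjusted over the list alone; Acta2 had 0.73, Tagln -0.11 and Myh11 0.90. Elongating spermatid markers had 0 of 6 called, and 3 adjusted over the list alone; Odf2 had -0.45, Akap4 -0.43 and Gapdhs -0.30.

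Among meiotic genes 8 of 59 rose in the first group of spermatocytes (adjusted p = 0.03643), and 20 were called adjusted over the list alone. Dmc1, the meiotic recombinase, had a log2 difference of 3.67 (SE 0.56), Sycp1 1.13 (SE 0.16) and Hormad1 0.98 (SE 0.17). Of 25 genes of the 7SK and U6 snRNP list 6 rose, among them Lsm8 (0.90) and Ssb (0.77), both of which bind U6 RNA, and Larp7 fell; for the rise the list had an adjusted p of 0.01039, and 10 genes were called adjusted over the list alone. Flagellum and cilium genes went the other way: 8 of 117 fell, among them Cfap70 (-0.83), Rsph10b (-0.85) and Cfap57 (-0.57), and 1 rose (adjusted p = 0.0001271 for the fall), with 10 called adjusted over the list alone. Chromatin regulators (9 of 83), splicing regulators (5 of 58), piRNA genes (2 of 26), acrosome genes (1 of 45) and core spliceosome genes (1 of 38) rose without passing adjustment as lists, and 11, 11, 4, 1 and 0 were called adjusted over the list alone. X-linked genes rose more often than others, at 26.9% of 175 against 4.31% of 9686 (Fisher's exact test, p = 1.95e-23). This test was not in the design. The examples Tktl1 (5.46), Tro (4.13) and Scml2 (3.73) were among the 8 genes with the smallest p. Leaving out the first library of the first group left 45 called genes and leaving out its second gave 1429, while without the first or second library of the second group 204 and 281 were called.

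In round spermatids 8 of 9315 genes were called for abundance, 7 higher in the first sample group and Larp7 lower. Nmnat3, an enzyme of NAD synthesis, was higher by 2.65 (SE 0.29) there and by 2.46 (SE 0.19) in spermatocytes. Fxyd2, a regulator of the sodium pump, was higher by 2.33 and by 2.35. Larp7, Nmnat3, Fxyd2, 1700049E15Rik and Churc1 were called in both stages, 5 genes where 0.36 are expected from independent lists. The limits given for shared splicing calls hold here too. With median-ratio scaling 1700049E15Rik, Churc1 and Gm10338 were no longer called in round spermatids. Gm10338, Gm21149 and Gm3115 were also called and belong to multicopy families, so their reads are uncertain. Of the lists, 7SK and U6 snRNP had Larp7 called, and the others had 0; adjusted over the list alone, 2 flagellum and cilium genes were called. None of the marker lists had a called gene by limma, also adjusted over the list alone. Stra8 differed by -0.07, Tuba3a by 0.07 and Sohlh1 by -0.45. Clu (0.73), Ctsl (0.67) and Espn (0.14), Tagln (0.59), Adgre1 (0.17) and Igf1 (0.58), and Akap4 (-0.57), Odf2 (-0.16) and Gapdhs (-0.38) did not pass the test. Without each library in turn the count was 131 and 1063 for the first group and 15 and 34 for the second.

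The stages themselves were compared with 4 libraries of both genotypes each. Of 34456 matched events 3775 in 2198 genes differed, 1574 of them by at least 10 percentage points. Retained introns were the clearest class: 722 of 2343 were called, 636 more retained in spermatocytes and 86 less (exact binomial test, adjusted p = 7.555e-104). Mean intron retention was 29% ± 0.711 (SD, n = 4) in spermatocytes and 25.7% ± 0.292 in round spermatids. SDs of the stage comparison pool both sample groups, so they also hold differences between these groups. An intron of Hnrnph1 (chromosome 11, 50379965 to 50382536) was retained at 52.5% ± 8.48 against 17.5% ± 5.12, and one of Arglu1, a splicing modulator, at 33.3% ± 4.78 against 7.78% ± 1.85. Cassette exons were more often lower in spermatocytes, with 1393 lower and 749 higher (adjusted p = 3.871e-44). Eef1d, an elongation factor subunit, had the event with the smallest p. Its 1140-nt exon (chromosome 15, 75902679 to 75903818) was included at 29.5% ± 8.60 in spermatocytes and 92.9% ± 2.35 in round spermatids. An exon of Pkm, pyruvate kinase (chromosome 9, 59663040 to 59663156), stood at 23.0% ± 8.79 against 89.0% ± 2.71, one of Kif2c at 4.38% ± 1.33 against 60.0% ± 10.7, and an alternative 5 prime site of Tex9 at 42.3% ± 5.16 against 5.19% ± 2.88. Alternative 5 prime sites leaned to spermatocytes (109 higher, 66 lower, adjusted p = 0.00238), and mutually exclusive exons and alternative 3 prime sites did not depart from an even split. Leaving out the second library of the first round spermatid group gave 1996 events, and 0.5 unscaled reads gave 5699.

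In list tests chosen after seeing the data, 38 of 58 splicing regulators differed between stages (65.5% against 25.6% of other genes, Fisher's exact test, adjusted p = 2.639e-09), which held with genes matched on coverage (adjusted p = 0.01864); 41 were called adjusted over the list alone. Rbm25 had an intron at 15.1% ± 3.99 against 6.11% ± 2.21, and an exon of Hnrnpll stood at 82.5% ± 4.30 against 58.9% ± 2.91. Of 114 flagellum and cilium genes 52 differed (adjusted p = 2.597e-05; 0.8786 with matched coverage), also 52 adjusted over the list alone, including Ift20 (45.2% ± 3.55 against 7.49% ± 2.41) and Spata17 (94.8% ± 1.48 against 66.6% ± 3.57). Other lists did not pass adjustment. In the 7SK and U6 list 8 of 22 differed (8 adjusted over the list alone), with Prpf31 at 12.7% ± 3.18 against 6.83% ± 0.875. The Larp7 intron stood at 18.9% ± 12.9 against 5.80% ± 2.45 and differed between the spermatocyte sample groups. Spermatocyte levels of the named Rbm25, Prpf31, Stag3 and Rnf17 events, among others, also did not overlap between the sample groups. In the core spliceosome 13 of 35 differed (13 alone), with an exon of U2af2 at 2.95% ± 0.620 against 39.8% ± 3.82 and an acceptor site of Snrnp70 at 28.7% ± 5.88 against 11.8% ± 2.50.

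Among meiotic genes 15 of 50 differed between stages (15 adjusted over the list alone), with an exon of Sycp1 at 99.0% ± 0.532 against 75.6% ± 8.08 and an intron of Stag3 at 5.62% ± 2.95 against 1.15% ± 0.323. Of piRNA genes 9 of 24 differed (9 alone), with Rnf17 at 94.9% ± 3.30 against 74.5% ± 2.44 and Gtsf1 at 3.17% ± 0.452 against 8.50% ± 2.16. Of acrosome and spermatid genes 17 of 44 differed (19 alone), with an intron of Catsperg1 at 58.0% ± 2.71 against 20.5% ± 1.63 and an exon of Meig1 at 51.2% ± 5.80 against 9.86% ± 1.68. Of chromatin regulators 24 of 80 differed (22 alone), with Brd2 at 11.8% ± 1.17 against 5.36% ± 0.647 and Brd3 at 94.0% ± 1.96 against 98.1% ± 0.324. Of 6 elongating spermatid markers Odf2 differed (90.5% ± 0.546 against 95.8% ± 0.798), the 1 gene also when adjusted over the list alone. Spermatogonia, Sertoli and Leydig, peritubular and immune markers had 0 called by limma, also adjusted over the list alone.

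**Figure D4:**
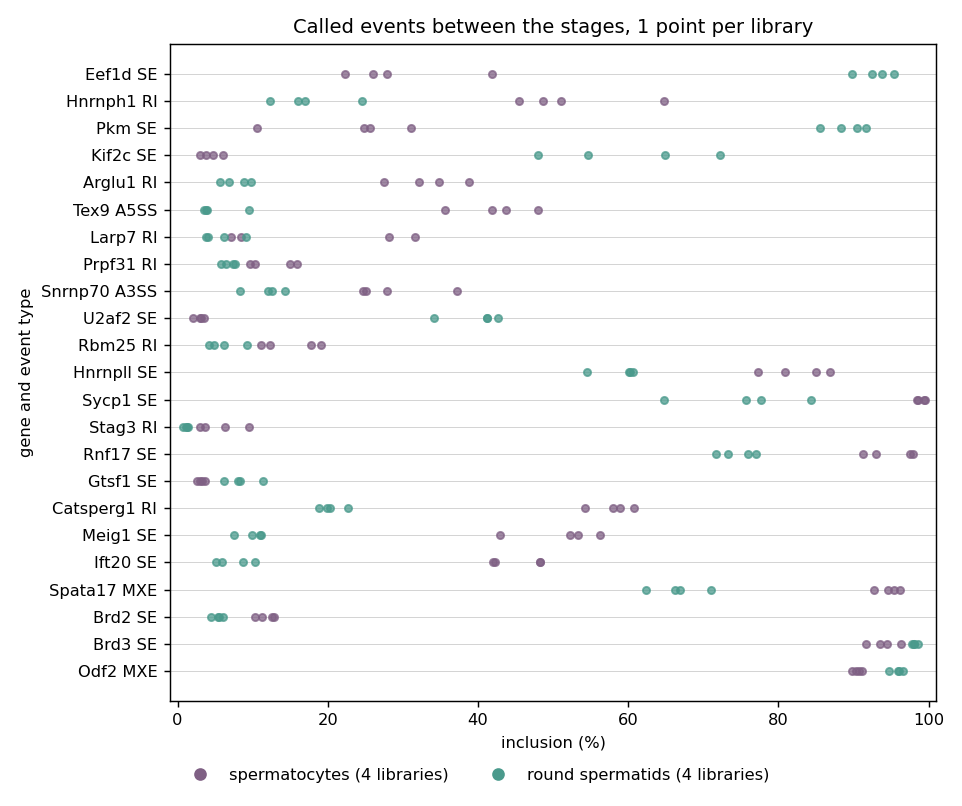
Inclusion in percent of the named events that differed between stages, 1 point per library and 1 line per event, with 4 spermatocyte and 4 round spermatid libraries. Libraries of the stages do not overlap except in the Larp7 intron; Eef1d stood at 29.5% against 92.9% on average.

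In the authors' deposited table, an FDR below 0.05 with an inclusion difference of at least 0.1 marked 1653 spermatocyte events in 1287 genes and 780 round spermatid events in 636 genes. Of these, 136 and 27 were also called by limma here, and 344 and 215 had under 10 reads per library on average. Cassette exons of the authors' deposited table were lower in the first group in 802 cases and higher in 262 in spermatocytes (exact binomial test, adjusted p = 3.566e-63), and lower in 329 and higher in 189 in round spermatids (adjusted p = 4.025e-09). In spermatocytes the authors' calls were also mostly lower among introns (126 lower, 76 higher, adjusted p = 0.001778) and among alternative 3 prime sites (75 lower, 40 higher, adjusted p = 0.003532), which the limma calls did not show for these sites.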

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

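The tests of exon-body reads, of make-up by abundance and of thinned depth were planned before their results were seen; those of marker genes, of the stage axis, of position correlation and of splits of the 8 libraries were chosen after. Among 58 sets of 4 libraries examined for a library far from the others, 2 stood out where chance gives about 2.9. One round spermatid library had 9.50% use of the Tex9 alternative 5 prime site against 3.51% to 3.99% in the others (gap over range 0.920). One round spermatid library included the Hnrnpll exon at 54.5% against 60.1% to 60.7% (0.902).

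The 3775 events between the stages came from the 4-group fit; in a 2-group fit the stages gave 3554, and 1 of the 35 ways to split the 8 libraries 4 against 4 gave as many, the real one, with at most 35 events in any other, which argues against a chance difference between sets of libraries.

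Lower inclusion of called cassette exons in the first spermatocyte group was not removed by equal depth: after thinning every library to the same number of event reads, 79.8% were lower (162 against 41). Fewer exon-body reads in that group are argued against as the whole cause, since 70.3% of exons under the median of 122 nt were lower, but the share was 92.9% among longer ones (Fisher's exact test, p = 4.08e-05), so a part for them stays open. Without genes called for abundance 93.5% of the called exons were left. The bound set beforehand took this to exclude a shift in cell make-up, but it was too loose, since 55.6% of genes spliced differently between stages differed by under 1 log2 in abundance; make-up therefore cannot be told apart from genotype. A less advanced cell mix may contribute: 76 of 83 called events that also differed between stages had the sign of spermatocytes minus round spermatids, but both differences use the first group, which favours a shared sign, and with the second group alone set against round spermatids, which favours opposite signs, 18 of 41 (43.9%) did.

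Higher abundance of 464 genes in the first spermatocyte group did not come from depth, since 98.5% of them were called higher again after thinning. Earlier germ cells in the gate are a candidate source: the spermatogonia markers had a median log2 difference of 2.66, against 0.16 for other genes. X-linked genes, a set that was not in the design, had 1.94. The first library of that group stood above its second, as in Stra8 (36.6 and 5.84 CPM against 1.60 and 2.15) and Uchl1 (99.4 and 27.4), and without it 45 genes were called for abundance, but the second library also lay above both libraries of the other group in these genes. Sertoli cells are another candidate source, with a median of 1.52, although sorting on Hoechst staining would be expected to leave such cells out, and Clu and Ctsl are not restricted to them. Both can hold at once, and a delay of meiosis with genotype stays open and untested.

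Position within the table cell divided the round spermatid libraries into sets with 335 called events, against 63 for the sample groups, which points to a structure of these libraries other than the sample groups. After thinning to equal depth the counts were 314 and 62, so depth is argued against. Position differences correlated across events between the sample groups (r = 0.225 over 11252 events, which are not independent). In spermatocytes, where position called 17 events, r was 0.101. Calls by position favour differences with the same sign in both groups. The correlation therefore restates the 335 calls and is no separate support for a shared preparation. A shared preparation may be behind them, but with no batch in the labels it cannot be told apart from a chance resemblance of libraries.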

How the results depend on the processing

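The genotype calls depend on how the spread is modelled. Alternatives on the trend, unscaled reads, rarer form, inclusion level and position, those without a library for abundance and for the share of cassette exons, and the stage list tests were chosen after seeing the data. In spermatocytes, against 322 calls, the trend on total reads gave 0, with or without unscaled 0.5 reads (17 to 3565 when robust moderation, a filter on the rarer form or the inclusion level, 8 libraries or position was added to the latter), no count weights 21, the quasi-binomial test 178 (39 with a trend on total reads), the 8-library fit 525, the authors' deposited FDR 2934, and 138 events also differed by at least 10 points. In round spermatids, against 63, the corresponding values were 0 (0 to 472), 28, 122 (9), 146, 1154 and 28; at least 5 reads of each form gave 32, inclusion between 5% and 95% gave 10 and position as a covariate 139. Leaving out a library gave 0 to 11517 in spermatocytes and 0 to 6663 in round spermatids. The cause was not tested. With unscaled reads cassette exons stayed mostly lower in the first group, in 77.7% of cases in spermatocytes and 68.8% in round spermatids. Fits without a library of the first group cannot test this direction. In them, exons without skipping reads in the second group have no spread left and are readily called lower in the first. Read minimum, 1 read added, unscaled reads and adjustment within type left between 300 and 357 calls in spermatocytes and between 58 and 69 in round spermatids.

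With matched coverage 0 lists passed for genotype and 1 for stage, and 0 with the authors' calls. Stage calls fell to 1574 with at least 10 points, rose to 5699 with unscaled reads and ranged from 1996 to 3115 without a library. Abundance calls ranged from 45 to 1429 in spermatocytes and from 15 to 1063 in round spermatids without a library; round spermatids gave 5 with median-ratio scaling and 14 summed over cassette events. The authors' calls fell to 907 and 372 at an FDR below 0.01 and to 816 and 469 with a difference of 0.2. Of 471 values for 60 named genotype events, 182 lost their call, 145 of them without a library, and 2 uncalled Larp7 values changed sign without the second library of the first group (0.948 and 0.943), against -2.305 and -2.417 without its first. All 253 values of 23 named stage events kept direction and call. The 60 named genotype events include Larp7 events that were not called in the reported fit and had no call to lose. The 182 of 471 values therefore understate the share of calls lost. A library left alone in its group was assumed to vary like the others.

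No paired analysis was possible because the columns carry no replicate numbers. The genotype by stage test and its alternatives were not run because the genotype order is not named. Changes of 1 unit of log2 odds were recovered in 14.3% of simulated spermatocyte events with 2 libraries per group. These events averaged at least 5 reads of each form, and recovery with fewer reads was not measured. How far depth sets the share recovered was not tested. Thinning to the smallest library left 332 calls in spermatocytes and 62 in round spermatids.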
